A study of Caenorhabditis elegans with 2 samples.

How the data were processed

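The series holds chromatin immunoprecipitation sequencing (ChIP-seq) of 1 group, whole Caenorhabditis elegans hermaphrodites of strain OR3350 at the fourth larval stage (L4), in 2 replicates. Per the labels, the animals were collected 55 h after synchronisation from starved first-stage larvae, and stably expressed HIF-1 with a GFP and FLAG tag at its C-terminal end. An anti-GFP antibody was used and chromatin was sheared by sonication. The replicates have separate biosamples and biological replicate numbers in the labels. The labels name no oxygen condition, and no other group was analysed here, so no comparison between conditions could be made. A control library entered the authors' peak calling, per the deposited descriptions, and was not used here.

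The authors deposited peak lists on 2 genome builds, ce10 and ce11. For each replicate, and for the pooled reads of both, there was a relaxed list of peaks and background meant as input for irreproducible discovery rate (IDR) analysis. A thresholded set of peaks that passed IDR was deposited for the series. Per the deposited descriptions, each relaxed list was made from alignments and 1 control. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The deposited lists give a signal value for each peak, which is the authors' own value relative to the control, with a formula that is not given in the sources used here. It was used only to describe and rank peaks within a list. The deposited lists also give a −log10 q-value per peak, which reaches a ceiling shared by the strongest peaks and so was not used for ranking. The summit is given as an offset from the peak start. The lists hold no read counts, so the sequencing depth is unknown and no interval that needs depth was computed.

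Peak positions were set against the WBcel235 assembly, which is ce11, and Ensembl release 115 gene models. All ce11 peak ends lay within the chromosome lengths of that assembly. Coordinates are 1-based and on ce11. The ce10 lists were compared by number and signal alone and no coordinates were converted. The thresholded ce11 set of 631 summits lies in 625 distinct intervals, since some intervals carry several summits, and each summit was counted as a peak.

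The following choices were made before the data were examined. The replicates were compared by their 631 strongest peaks each, taking summits within 100 bp as shared, against 1000 random placements on the same chromosomes (one-sided permutation test). Each summit of the thresholded set was assigned to a promoter (1000 bp upstream to 200 bp downstream of a protein-coding gene start), otherwise to an exon, an intron or other sequence, and the shares were compared with 1000 random placements (two-sided permutation test). The core of the hypoxia response element, RCGTG with R for A or G, was searched on both strands within 50 bp of the summit and in flanks of the same size centred 500 bp to either side, with exact McNemar tests, two-sided. Its presence was correlated with signal over peaks with 100000 permutations. All sequences of 6 bases were tested at summits against flanks with two-sided Fisher exact tests. Genes were called bound when a summit lay in the promoter window, and 33 gene lists were each tested against all other protein-coding genes with two-sided Fisher exact tests. Classes of noncoding RNA genes were tested in the same way against all annotated genes, with a window of 500 bp upstream to 200 bp downstream. Peaks per chromosome were tested with exact binomial tests on chromosome length. Benjamini-Hochberg adjustment was applied within each family, and shares have 95% Wilson intervals, which cover the number of peaks or genes only. Of the list members, 14 names matched no annotated gene.

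The named genes were set by a rule. They are the genes at the 20 peaks with the highest signal, all members of the lists of HIF-1 regulators and of genes described as dependent on HIF-1, the 6 strongest bound members of each other list past an adjusted p of 0.05, and at most 3 bound members of the remaining lists. Genes outside this rule are named as chosen after their values were seen. Because 13 of the 20 strongest peaks were mitochondrial, a listing of the 20 strongest nuclear peaks and a repeat of the results on nuclear chromosomes alone were added after seeing the data.

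Alternatives covered the distance and number of peaks in the replicate comparison, the ce10 lists, the promoter window, assignment to the nearest gene start, the stronger 50% of peaks, each replicate alone, local placement, the search window and form of the core, shuffled summit sequences, gene lists matched on gene spacing with 10000 draws, and peaks per protein-coding gene. The steps were tested on simulated data. With 631 simulated peaks, planting gave an expected core share of 50.3% and 51.2% was found, an expected promoter share of 44.0% gave 44.2%, all 300 planted shared peaks of 2 lists were found, and 0 sequences of 6 bases were called without planting. The peaks without planting lay at random positions. The 0 calls therefore do not cover the difference in GC content between the real summits and their flanks. The work used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Random placement takes no account of mappability or open chromatin, peaks and genes are not independent replicates, and 1 peak can serve several genes.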

Results

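HIF-1, the worm hypoxia-inducible factor, is a transcription factor that binds DNA with its partner AHA-1 and is degraded when oxygen is plentiful. Its binding was mapped in whole L4 hermaphrodites of 1 group with 2 biological replicates, using an antibody against the GFP tag on HIF-1. The relaxed peak lists on ce11 held 13935 peaks for replicate 1, 13823 for replicate 2 and 6541 for the pooled reads. The thresholded set held 631 peaks, of which 612 were nuclear and 19 mitochondrial. Their signal values ran from 54.1 to 2272.69 with a median of 77.8, and the 631 were the highest-signal entries of the pooled list. The sequencing depth is unknown, and signal values are the authors' own.

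The question of whether the replicates marked the same places was answered with their 631 strongest peaks each. The peaks of rhy-1, nhr-57 and sqrd-1, described below, ranked 7, 11 and 16 in replicate 1 and 10, 20 and 19 in replicate 2. Ranks differed more for some weaker peaks at genes named below. In replicates 1 and 2 they were 621 and 82 for cdo-1, 502 and 130 for oac-54, and 255 and 1650 for ipgm-1. Of the 631 strongest peaks of replicate 1, 367 (58.2%) had a summit within 100 bp of one in replicate 2, against a mean of 6.09 and a maximum of 13 in random placements (one-sided permutation p = 0.001, the smallest that 1000 placements can give). Over the 367 shared peaks the signal values had a Pearson r of 0.951 and a Spearman rho of 0.761, across peaks, which are not independent replicates. For the 348 nuclear ones these were 0.921 and 0.741. Of the 631 thresholded peaks, 365 were among the 631 strongest of both replicates, and 596 (94.5%) had a summit in both relaxed lists, which is not a separate test because the set was chosen for reproducibility between these replicates.

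**Figure D1:**
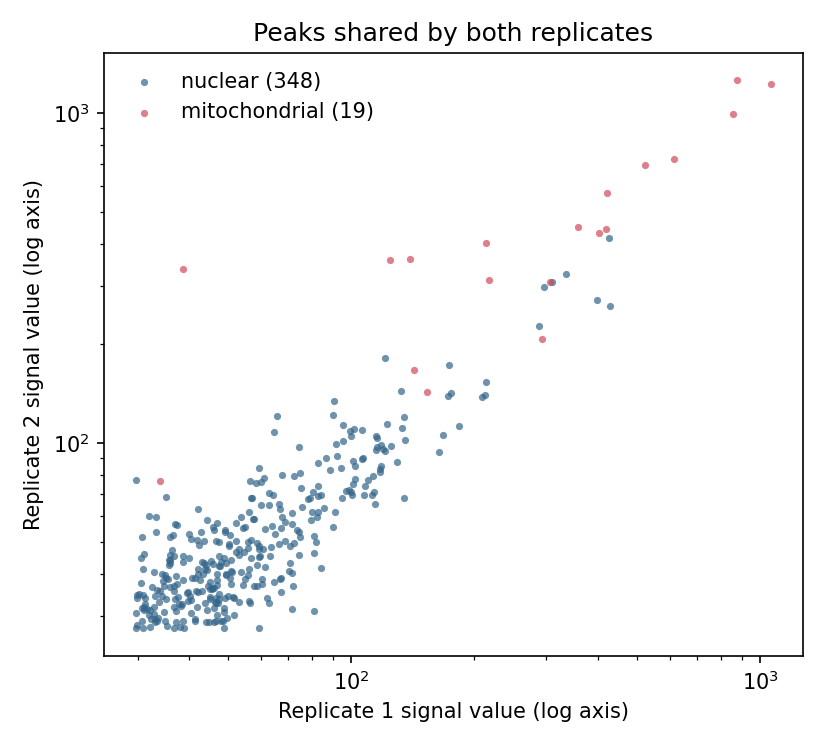
Signal value in replicate 2 against replicate 1, both on log axes, for the 367 peaks shared by the 631 strongest of each replicate; blue points are nuclear (348) and red points mitochondrial (19). The points rise together (Pearson r 0.951 on signal values), with the mitochondrial peaks reaching the highest values.

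Among the strongest nuclear peaks were those at genes that regulate HIF-1 or were already described as dependent on it. The highest had a signal of 838 and a summit 938 bp upstream of rhy-1, a negative regulator of HIF-1 (chromosome II, 9160215 to 9160767). The next, with 688, lay outside genes 1744 bp upstream of egl-9, the prolyl hydroxylase that marks HIF-1 for degradation (chromosome V, 10466542 to 10466957). A further peak of 122 lay in the egl-9 promoter, 139 bp upstream of the gene start. Peaks followed at the promoters of the nuclear hormone receptor gene nhr-57 (670, chromosome V, 4131423 to 4131946) and of sqrd-1, which encodes a sulfide quinone oxidoreductase (590, chromosome IV, 14219664 to 14220036, 30 bp upstream of the gene start). The plus-strand sequence centred on the rhy-1 summit was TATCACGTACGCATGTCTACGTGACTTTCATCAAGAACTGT, and on the sqrd-1 summit it was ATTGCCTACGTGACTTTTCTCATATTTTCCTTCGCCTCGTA.

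Of the 17 listed genes described as dependent on HIF-1, 10 were bound at the promoter (58.8%, 95% Wilson interval 36.01 to 78.4), against 1.92% of other protein-coding genes (odds ratio 72.9, adjusted p = 4.49e-12, Fisher exact test). Besides rhy-1, nhr-57, sqrd-1 and egl-9 these were pck-1 (272), the gluconeogenic phosphoenolpyruvate carboxykinase gene, gst-19 (222.02), the persulfide dioxygenase gene ethe-1 (140), the cysteine dioxygenase gene cdo-1 (127), the acyltransferase gene oac-54 (93.7) and dhs-8 (59.4). Outside the promoter window, cysl-2, which encodes a cysteine synthase-like enzyme, had a peak of 198 at 1127 bp upstream, and F22B5.4 had one of 256 in an intron, 1918 bp downstream of its start. The ferritin gene ftn-2 had a peak of 69.2 at 1157 bp upstream, and phy-2, which encodes a collagen prolyl 4-hydroxylase subunit, one of 67.9 at 2486 bp upstream. RCGTG lay within 50 bp of the summit at 8 of the 10 promoter peaks, the exceptions being ethe-1 and dhs-8. In all, 14 of the 17 had a thresholded summit within 2500 bp of the gene start. With a promoter window of 500 bp upstream to 100 bp downstream 5 of the 17 were bound (29.4%), and 13 (76.5%) when each summit was given to the nearest gene start, and the list stayed past the threshold in both (Fisher exact adjusted p = 5.23e-05 and 2.99e-16). No thresholded peak lay within 2500 bp of fmo-2, ftn-1 or smf-3. The list came from general knowledge, and whether earlier work on any member used these libraries was not checked.

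Of the 12 listed members of the HIF-1 pathway, rhy-1 and egl-9 were bound at the promoter (2 of 12, Fisher exact adjusted p = 0.0674), and the call passed the threshold with a promoter window of 2000 bp upstream to 500 bp downstream (3 of 12, adjusted p = 0.0108), with the nearest gene start (3 of 12, adjusted p = 0.0154) and in the stronger 50% of peaks (2 of 12, adjusted p = 0.0201). The hif-1 gene had its nearest thresholded peak 2017 bp upstream (146, chromosome V, 20778168 to 20778611), without RCGTG within 50 bp of the summit. This is the locus of the tagged gene, and the 40 kb around it held 14 and 22 relaxed-list peaks in replicates 1 and 2, against a median of 4 in random windows of the chromosome. The ubiquitin ligase gene elc-1 had a peak of 57.1 at 1719 bp upstream, and the chaperone gene hsp-90 one of 121 at 864 bp downstream of its start. These summits lay in the promoter windows of other genes, Y82E9BR.3 and C47E8.4, which are named after the values were seen. The genes aha-1, vhl-1, cul-2, elb-1, rbx-1, cysl-1 and swan-1 had no thresholded peak within 2500 bp. In the pooled relaxed list aha-1 and cysl-1 had weak promoter peaks (24.4 and 25.1).

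**Figure D2:**
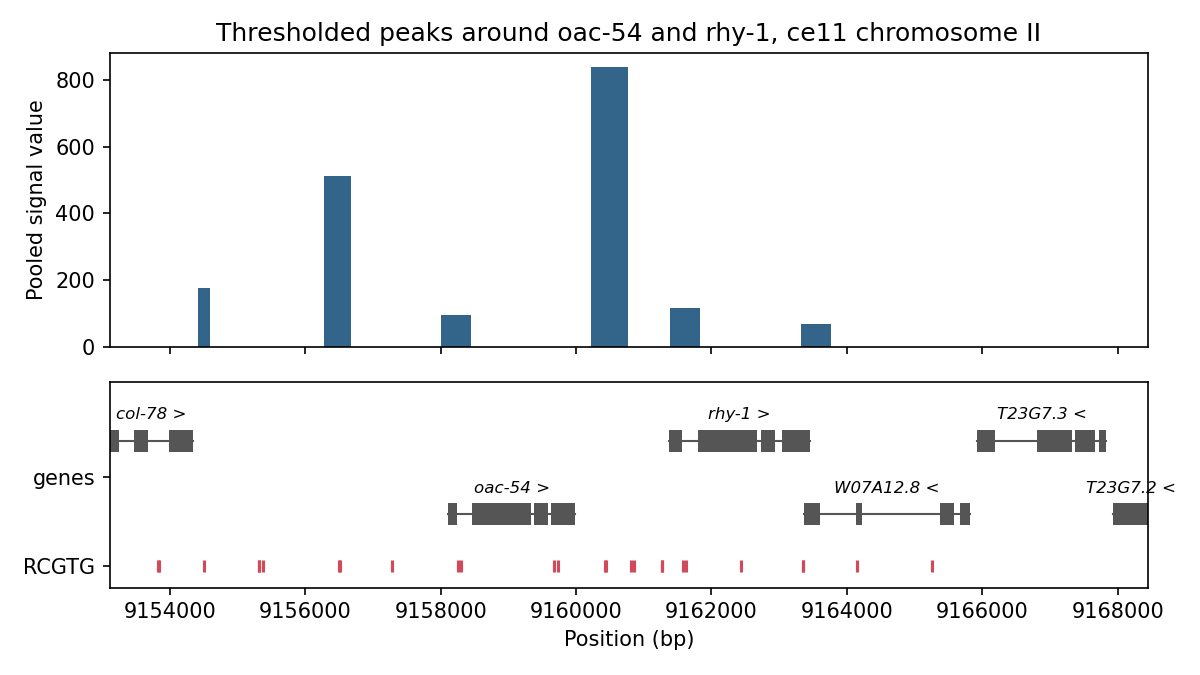
Map of oac-54 and rhy-1 on ce11 chromosome II (position in bp); bars in the upper panel are thresholded peak intervals with their pooled signal value, the lower panel shows exons of protein-coding genes with arrows for strand, and red ticks are RCGTG on either strand. Where an interval carries several summits its strongest is drawn, and the tallest bar is the peak of 838 upstream of rhy-1.

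Of the 20 strongest peaks, 13 were mitochondrial and 7 nuclear. The mitochondrial summits lay in the genes ND5 (2272.69, the highest signal of the set), CYTB, COX3, COX1, ND4, COX2 and ATP6, which encode respiratory chain and ATP synthase subunits, and in rRNA and tRNA genes. The 19 mitochondrial peaks covered 46.4% of the 13794 bp mitochondrial genome, whereas the nuclear peaks covered 0.255% of the nuclear genome, and 2 of the 19 held RCGTG. Whether this mitochondrial signal reflects binding of HIF-1 was not tested. The other nuclear peaks among the 20 were a peak of 649 in an intron of ZK470.2, with ZK470.4 as the gene of the nearest start, a peak of 614 at the promoter of F26H9.5, a putative phosphoserine aminotransferase gene, and a peak of 512 located 1634 bp upstream of oac-54. The listing of the 20 strongest nuclear peaks, chosen after the values were seen, added peaks in introns of Y62E10A.13 (366), H18N23.2 (352), hlh-30 (304), ppfr-1 (273), F22B5.4 and gnrr-3 (254), and at the promoters of rpl-3 (342), tasp-1 with K01G5.10 (320), mai-1 (294), pck-1 and taap-1 (247). Another lay near nspe-6 (343), and a further peak lay at the F26H9.5 promoter (320). All 20 had a summit in both relaxed lists, and 16 of the 20 held RCGTG.

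Peaks were compared with random placement to ask where in genes HIF-1 bound. Promoters held 310 of the 631 summits (49.1%, 95% Wilson interval 45.2 to 53.0), against 22.7% ± 1.57 (SD over 1000 placements), a ratio of 2.16. On nuclear chromosomes alone the promoter share was 48.2% (random 21.1%). Exons held 29 (4.60%, random 22.96%) and introns 124 (19.7%, random 29.6%), both fewer than random (permutation test, adjusted p = 0.00266 for promoters, exons and introns, the smallest the placements can give). Other sequence held 168 (26.6%, random 24.7%, permutation test adjusted p = 0.318). Summits of the 295 nuclear promoter peaks lay at a median of -220 bp relative to the gene start, 28 of all summits lay in a 5′ UTR and 7 in a 3′ UTR, and 105 lay at promoters of 2 or more genes. With a promoter window of 500 bp upstream to 100 bp downstream, the share in other sequence was 36.5% (random 29.7%, permutation test adjusted p = 0.002). The exon share was 7.13% without replicate 1 and 2.85% with a window of 2000 bp upstream to 500 bp downstream, below random in both.

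RCGTG, the core that HIF proteins bind, was present within 50 bp of 289 of the 631 summits (45.8%, 95% Wilson interval 41.95 to 49.7), against 11.9% of the left and 15.4% of the right flanks (exact McNemar p = 1.33e-38 and 2.18e-32). With the bases of each summit window shuffled, which keeps its base composition, the mean share was 25.6% (permutation p = 0.000999). ACGTG was present at 28.1% of summits against 8.95% of flanks, and GCGTG at 22.3% against 5.31%. The nearest core lay at a median of 22 bp from the summit where there was one, and 109 peaks held 2 or more. In 5 equal bins from the strongest to the weakest peaks, the share with RCGTG was 54.3%, 47.6%, 49.2%, 40.5% and 37.3%. The first bin, of 127 peaks, held 18 mitochondrial ones. Presence rose with signal across peaks (Spearman rho 0.117, permutation p = 0.00325, two-sided, 631 peaks), but for the strongest peaks of replicate 1 alone, without replicate 2, rho was 0.0539 (p = 0.175), and without replicate 1 it was 0.178. On nuclear chromosomes alone, a setting added after the results were seen, rho was 0.16 (permutation p = 7e-05). Within 25 bp of the summit 24.7% of peaks held RCGTG against 6.89% of flanks, and within 200 bp 77.2% against 44.6%. The 20 strongest peaks, 13 of them mitochondrial, held it in 45% of cases, against 20% of the right flanks (exact McNemar p = 0.18) and 5% of the left (p = 0.0215). The 20 strongest nuclear peaks held it in 80%, against 20% of either flank (exact McNemar p = 0.000488 right and 0.00183 left).

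**Figure D3:**
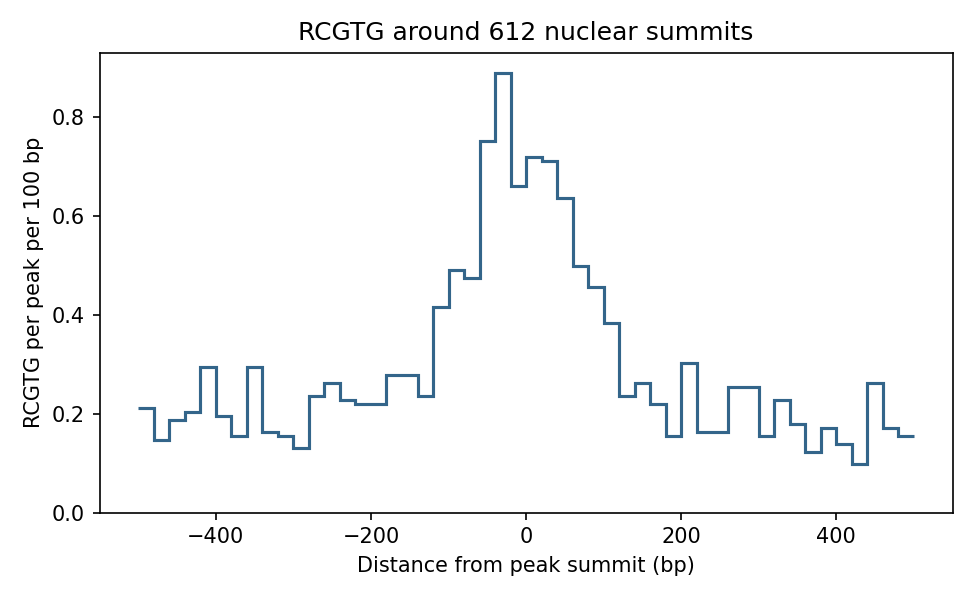
Number of RCGTG sequences per peak per 100 bp (vertical axis) by distance from the summit in bp (horizontal axis, bins of 20 bp) over 612 nuclear peaks. The density is highest within about 50 bp of the summit and lower in the flanks at 500 bp.

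The open search covered 2080 sequences of 6 bases, with reverse complements merged. Of these, 479 were more frequent at summits than in flanks and 306 less frequent (adjusted p under the threshold of 0.05, Fisher exact test), and all 16 that contain the core were among the 479. Sequences with CpG, which every sequence with the core has, made up 274 of the 479, so a higher share at summits was not particular to the core. TGCGTC was at 15.2% of summits against 1.27% of flanks, GAGAGA at 23.9% against 6.10%, and TACGTG, which contains the core, at 12.7% against 1.98%. Summits of nuclear peaks had a GC content of 47.5%, and their flanks 36.1% and 35.7%. With a window of 25 bp, 308 sequences were more frequent at summits.

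Gene lists were tested to ask which groups of genes HIF-1 bound. Of 19985 protein-coding genes, 394 (1.97%) had a summit at the promoter, 10 of them mitochondrial genes. Of the 33 lists, 10 passed an adjusted p of 0.05, 8 with more and 2 with fewer bound genes than the rest. The same 10 lists passed on nuclear chromosomes alone. In glycolysis and gluconeogenesis, 6 of 27 were bound (22.2%, Fisher exact adjusted p = 7.78e-05), namely pck-1, the aldolase gene aldo-1 (127), the pyruvate carboxylase gene pyc-1 (112), pdhk-2 (75.1), ipgm-1 (71.8) and hxk-3 (63.9), and all 6 peaks held RCGTG, which 46.1% of all promoter peaks held. In the respiratory chain, 7 of 36 were bound (19.4%, Fisher exact adjusted p = 4.61e-05), led by the succinate dehydrogenase subunit genes sdha-1 (221) and mev-1 (159) and by cox-5A (165), atp-1 (92.9), cox-5B (81.1) and ucr-2.1 (68.0), and 3 of the 7 peaks held RCGTG. In the citric acid and glyoxylate cycles, 4 of 22 were bound (18.2%, Fisher exact adjusted p = 0.00339), which were sdha-1, mev-1, mdh-1 (153) and aco-2 (83.6), all 4 with RCGTG. In sulfur metabolism, 4 of 29 were bound (13.8%, Fisher exact adjusted p = 0.00877), which were sqrd-1, ethe-1, cdo-1 and mpst-3 (105), 3 of the 4 with RCGTG. These lists share members, and 1 peak each at sdha-1 and mev-1 counts in both energy lists. The bound sulfur genes sqrd-1, ethe-1 and cdo-1, and pck-1 of glycolysis, are also on the list of genes described as dependent on HIF-1.

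Ribosomal protein genes were bound in 17 of 81 cases (20.99%, 95% Wilson interval 13.5 to 31.1, Fisher exact adjusted p = 4.88e-12), led by rpl-3 (342), rpl-20 (220), rpl-35 (212), rpl-15 (198), rps-1 (141) and rpl-12 (136), and 10 of the 17 peaks held RCGTG. Of heat shock and cytosolic chaperone genes, 5 of 23 were bound (21.7%, Fisher exact adjusted p = 0.000401). These were F44E5.4 and F44E5.5, HSP70 genes that share 1 peak (144), dnj-13 (118.6), hsp-110 (114) and hsp-1 (103), and 1 of their 4 distinct peaks held RCGTG. Of genes of the unfolded protein responses, 4 of 20 were bound (20%, Fisher exact adjusted p = 0.00265), which were hsp-60 (129), hsp-3 (90.1), xbp-1 (79.6) and pdi-3 (62.7), all 4 with RCGTG. Chemoreceptor genes were bound less often than other genes (5 of 1241, 0.403% against 2.08%, Fisher exact adjusted p = 2.54e-05), the strongest being srw-67 (103), srh-17 (81.0), sre-23 (70.2), srh-70 (67.0) and sri-5 (59.0), and all 5 peaks held RCGTG. Of C-type lectin and lysozyme genes 0 of 256 were bound (upper Wilson limit 1.48%, Fisher exact adjusted p = 0.0362). With a promoter window of 500 bp upstream to 100 bp downstream the unfolded protein list was no longer called (Fisher exact adjusted p = 0.121) and neither were the lectins (adjusted p = 0.185), which were also lost without replicate 1 (adjusted p = 0.0547) and in the stronger 50% of peaks (adjusted p = 0.52). With the nearest gene start neither the unfolded protein list (adjusted p = 0.283) nor the citric acid list (exact test, adjusted p = 0.0704) was called. Shares moved without loss of the call for glycolysis (37.04% with the wider window, 11.1% in the stronger 50% of peaks), sulfur metabolism (24.1% with the wider window), ribosomal proteins (12.35% in the stronger 50% of peaks) and chemoreceptors (0.645% by nearest gene start, 0.161% in the stronger 50%). In the stronger 50% the share of genes outside the ribosomal list also fell, to 0.95%. By nearest gene start 10 of 81 ribosomal protein genes were bound (Fisher exact adjusted p = 0.000471).

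**Figure D4:**
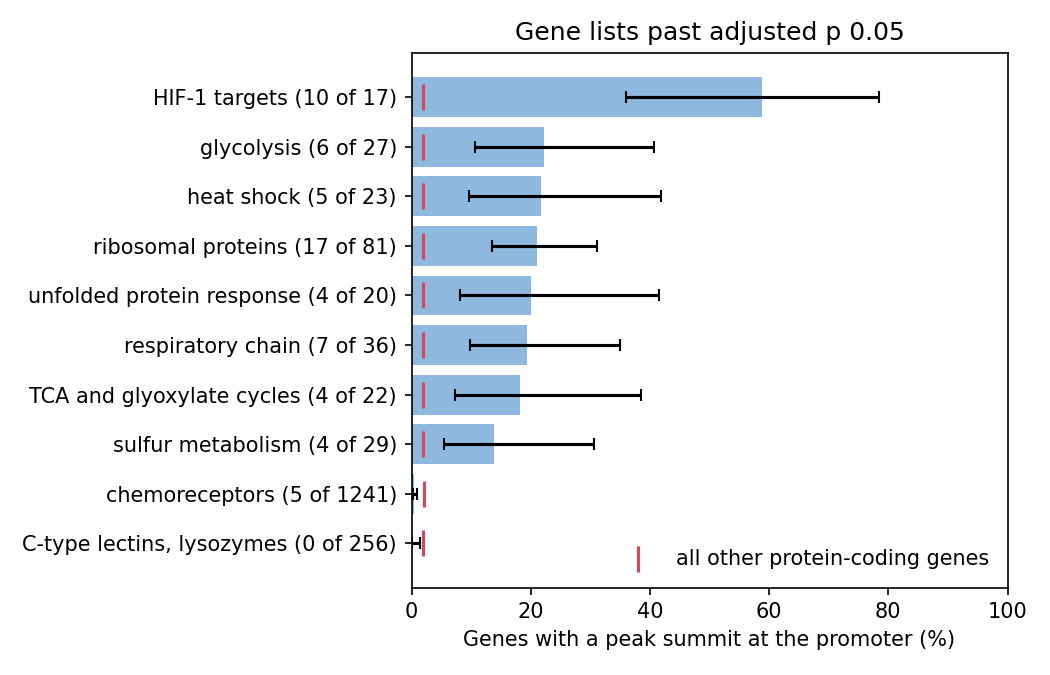
Percentage of genes with a peak summit at the promoter (horizontal axis) for the 10 lists past an adjusted p of 0.05; bars are the lists, error bars 95% Wilson intervals, and red marks the share among all other protein-coding genes. The list of genes described as dependent on HIF-1 stands highest (58.8%), and chemoreceptors (0.403%) and C-type lectins and lysozymes (0 of 256) lie below the red marks.

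The markers of intestine, body wall muscle, pharynx, neurons, hypodermis and germline had 0 bound genes each, as did the lists of collagens, cytochrome P450 genes, neuropeptides and metal handling. None of these passed the test (adjusted p from 0.219 to 1), and lists of 21 to 156 genes leave wide intervals. The remaining lists also did not pass. Nuclear hormone receptors were bound in 6 of 269 cases (nhr-57, nhr-47 and nhr-1 being strongest) and F-box and related genes in 6 of 395 (fbxb-58, fbxb-85 and fbxb-72). Among oxidative stress genes wdr-23 and dhs-8 were bound, among proteasome genes rpn-3 and rpn-6.1, and among homeobox genes ceh-99 and ceh-38. Single bound members were pdi-6 of matrix genes, gcy-33 of oxygen sensing, ftt-2 of insulin signalling, lgg-2 of autophagy, dgat-2 of lipid genes, gst-19 of transferases and his-37 of histones. Some of these share a peak with a gene of another list. The peak of rpn-3 is that of hsp-110, the peak of ceh-99 is that of srh-70, and the peak of dgat-2 also serves an F-box gene.

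Noncoding RNA genes were tested because such classes are known to draw unspecific signal. A summit lay in the window of 69 of 634 tRNA genes (10.9%, Fisher exact adjusted p = 3.89e-41), 39 of 346 snoRNA genes (11.3%, adjusted p = 3.68e-24) and 9 of 129 snRNA genes (6.98%, adjusted p = 7.81e-05), against 1.17%, 1.23% and 1.29% of other genes. Other noncoding genes were bound less often (0.811%, Fisher exact adjusted p = 7.63e-21), and miRNA genes (7 of 261, adjusted p = 0.106) and rRNA genes (1 of 22, adjusted p = 0.251) did not differ detectably, although miRNA genes passed without replicate 2 (9 of 261, adjusted p = 0.00746). miRNA genes also passed with a window of 1000 bp upstream to 200 bp downstream (11 of 261, Fisher exact adjusted p = 0.00565). When the summit had to lie in the gene itself, the snoRNA (Fisher exact adjusted p = 0.473) and snRNA (adjusted p = 0.0671) calls were lost, the tRNA share was 2.84% and still past the threshold, and rRNA genes passed (2 of 22, adjusted p = 0.0158). Mitochondrial summits lay in the rRNA genes KEF34_r01 and KEF34_r02 and in a tRNA gene. On nuclear chromosomes alone 0 rRNA genes had a summit in the promoter window, and the test by gene body was not run there. In the stronger 50% of peaks the shares were 4.101% for tRNA, 4.34% for snoRNA and 5.43% for snRNA genes, and on nuclear chromosomes alone 56 tRNA genes were bound (8.83%), all still past the threshold.

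Chromosome X held 8.07 peaks per Mb, 1.32 times the number its length gives (143 peaks, adjusted p = 0.00111), and chromosome V held 4.35 per Mb, 0.713 times (91 peaks, adjusted p = 0.00111, exact binomial tests). Chromosomes I to IV did not pass. With the stronger 50% of peaks the call on chromosome V was lost (ratio 0.745, exact binomial adjusted p = 0.0526) and chromosome I passed (ratio 0.652, adjusted p = 0.0342).

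The same libraries processed on ce10 gave 707 thresholded peaks, 76 more than on ce11 (12.04%), of which 687 were nuclear and 20 mitochondrial. Their median signal was 71.4, and 143 peaks on chromosome X on ce11 stood beside 167 on ce10.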

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

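The tests of CpG content in the 100 strongest nuclear peaks and of composition at the summits by noncoding genes were chosen only after the results were seen; for the ribosomal and respiratory genes, the list results had been seen but not the tested values. The design has 1 group, so no biological difference between groups was tested.

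RCGTG was also more frequent at summits than in flanks among the weaker peaks of the pooled list. Of the 5910 pooled-list peaks below the threshold, 1 lacked a full flank and was left out. Of the other 5909, 22.2% held RCGTG within 50 bp of the summit, against 13.9% of their flanks (exact McNemar p = 8.71e-36 and 7.72e-28 against the right and left flank). No shuffled windows were computed for these peaks, so base composition may account for this excess. At the thresholded summits shuffled windows held RCGTG in 25.6% of cases.

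RCGTG was enriched at summits. Base composition may account for part of this, since it alone gave RCGTG in 25.6% of shuffled summit windows, against 45.8% as found. The bases were shuffled singly, which does not keep CpG content, so CpG content of summits in general was examined through other sequences. Of 114 other sequences of 5 bases with 1 CpG, 92.1% had a lower summit to flank ratio than RCGTG, short of the 95% set in advance. Taken singly, GCGTG (ratio 4.21) lay above the 95th percentile of the others (4.11) and ACGTG (3.13) did not, with 12 others at or above it. The others with a higher ratio than RCGTG include CGTGC (3.76), which overlaps the core, and GACGC (4.87), a part of TGCGTC. The comparison therefore does not measure CpG content alone and cannot decide the question. In the 100 strongest nuclear peaks RCGTG was at 61.0% of summits and the most frequent other such sequence at 37%, but by ratio only 87.7% of the others lay below it, and RCGTG joins 2 sequences while each other is 1. A shared sequence with no link to peak strength is argued against by the rise of the core with signal over all 631 peaks (Spearman rho 0.117). Without replicate 2, however, rho was 0.0539 (permutation p = 0.175). The correlation was not run on promoter peaks alone, so a sequence of promoters in particular was not tested. CpG content therefore stays open for GCGTG, for ACGTG and for RCGTG as a whole. Other sequences, such as CGCAG (ratio 4.95), had a higher ratio than GCGTG.

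Peaks at tRNA, snoRNA, snRNA, ribosomal protein and respiratory chain genes may in part be unspecific signal at highly transcribed genes. At the 95 nuclear summits by those noncoding genes 31.6% held RCGTG, more than their flanks (11.6%, exact McNemar p = 0.000912 and 0.000821) and fewer than the 49.7% of other nuclear peaks (Fisher exact p = 0.00115). The bound set in advance against unspecific signal was thus met, but it took no account of composition: the same windows held RCGTG in 29.4% of cases after shuffling their bases (permutation p = 0.352), and 40 of 114 other sequences with 1 CpG had a ratio of summit to flank there at or above its 2.73. At the 24 ribosomal and respiratory summits 54.2% held RCGTG (exact McNemar p = 0.0654 and 0.00342 against the right and left flank). Of other nuclear promoter summits 47.2% held it (Fisher exact p = 0.531). TGCGTC was at 29.2% of the 24 summits against 17.3% of other nuclear promoter summits (Fisher exact p = 0.168). For both groups of genes unspecific and specific signal cannot be told apart, since base composition gives about the same share at the first, 24 summits are few at the other, and no untagged control was used here.

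Extra copies of the tagged region are a candidate source of the peaks around hif-1, although a control with the same copies would reduce such signal. Around hif-1, both relaxed lists held more peaks than at least 98.2% of random 40 kb windows of the chromosome, although a bin of 5 kb located 70 kb upstream held 5 and 4 peaks, as many or nearly as many as the densest bin next to hif-1. A cluster of HIF-1 sites there was tested by its share of RCGTG in the pooled list, 18.8% of 16 peaks against 24.5% of other nuclear peaks (Fisher exact p = 0.775), which leaves it open.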

How the results depend on the processing

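The results restricted to nuclear chromosomes and the test on the 20 strongest nuclear peaks were chosen only after the results were seen. Of 60 values under alternatives for the results that answer a comparison, 57 kept their direction and side of the threshold or stayed within 1.5 times the count. The exceptions were the core in the 20 strongest peaks (45%, p = 0.18 against the right flank and 0.0215 against the left; 13 were mitochondrial, and the 20 strongest nuclear peaks gave 80%; the cause was not tested), the link of the core to signal without replicate 2 (rho 0.0539, the cause was not tested), and the sequences of 6 bases with a 25 bp window (308 against 479, the narrower window holding fewer bases; 297 were shared). With each replicate left out in turn, the range was 0.0539 to 0.178 for that rho, 426 to 461 for sequences, 43.1% to 48.2% for the core, 46.9% to 49.3% for promoters, 4.28% to 7.13% for exons, 9 to 10 for lists, 4 to 5 for noncoding classes and 2 to 2 for chromosomes. The shared percentage of the replicates ran from 44.5% to 68.3% over its alternatives. Among single lists, classes, parts and chromosomes, 156 values were the same, 8 passed newly, 9 were lost and 2 reversed. The reversed values were miRNA genes by overlap with the gene itself (0%) and rRNA genes on nuclear chromosomes (0%), where 0 genes were bound. All 10 lists passed also when matched on gene spacing. The ce10 chromosome test used the ce11 lengths. No paired analysis was possible because there is 1 group. The unknown depth limits any statement about weak sites.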

Other observations

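The genes in this part were chosen, and the test of RCGTG at promoters was set, only after the results were seen. The 3 enzymes that make serine from a glycolytic intermediate each had peaks among the 50 strongest nuclear ones. F26H9.5, the putative phosphoserine aminotransferase gene, had promoter peaks of 614 and 320 (ranks 15 and 27) and weaker exon peaks of 64.5 and 56.9 (ranks 437 and 575). Y62E10A.13, the phosphoserine phosphatase gene, had intron peaks of 366 and 220 (ranks 23 and 44), and phdh-1, the phosphoglycerate dehydrogenase gene, had a promoter peak of 215 (rank 46). The 5 strong peaks ranked from 14 to 46 in replicate 1 and from 18 to 54 in replicate 2, while the exon peaks ranked 702 and 10216 in replicate 1. Of the 7 peaks those of 614, 220, 215 and 56.9 held RCGTG, and those of 366, 320 and 64.5 did not. The pathway was picked from the peaks, and it was not tested for enrichment.

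Some other genes with strong peaks are given as values, with no list tested. The worm TFEB gene hlh-30 had an intron peak of 304 with 3 cores, skn-1, the worm Nrf gene, an intron peak of 179, and mml-1, a Myc and Mondo-like gene, a peak of 156 with 3 cores located 1874 bp upstream. The histone demethylase genes jmjd-1.2 and rbr-2 had promoter peaks of 193 each, the former shared with mrps-21 and F29B9.11. The cysteine synthase gene cysl-3 had a peak of 167 located 1046 bp upstream, and the peaks at skn-1, jmjd-1.2, rbr-2 and cysl-3 held 1 core each. Peaks with RCGTG were not detectably more often at promoters than those without (49.1% against 47.4%, Fisher exact p = 0.686).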
